A study of Macaca fascicularis with 3 samples.

How the data were processed

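Single-cell RNA of EOM and single-nucleus RNA of EOM and QFM were measured in 3 libraries, sequenced as paired reads on a NovaSeq instrument per the labels' protocols, which also name poly-T beads. Groups were taken from the sample titles. The QFM title says nuclei while the names of its files say single cells, and if the files were right every EOM against QFM ratio would also compare nuclei with cells. The labels do not say how many animals were used. The deposited values are raw UMI counts per gene and barcode, and every deposited barcode held at least 500 UMIs. Both nuclei tables were made with Cell Ranger 7.2.0, per the file headers. The submitters' processing notes name Cell Ranger 7.2.0 and Seurat 5.2.1 for all samples, without saying which step each served. The genome build, the annotation release and whether intronic reads were counted are not given in the sources used here. The nuclei tables list 38550 features, of which 22005 carry a gene symbol and 16545 an Ensembl identifier only. The cell table lists 33368 features with names in the style of NCBI; 17413 were named in the file, 793 were named by NCBI gene identifier and 2 by an older symbol, using an NCBI gene table of the species for names only. Both kinds of table share 13945 symbols. Of 313 distinct genes on the lists, 73 have no symbol in the nuclei tables and were not analysed here, among them MYH1, MYH2, MYH8 and RYR1. The class markers TTN and CKM, which are not among these 73, have no symbol there either.

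Barcodes were kept with at least 200 genes and 500 UMIs and a mitochondrial share of at most 10% in nuclei and 20% in cells, which left 16473 EOM nuclei, 12391 QFM nuclei and 7299 EOM cells. Scrublet, as built into scanpy, with an expected rate of 6% called 2503 doublets (15.2%) in EOM nuclei, 1863 (15.0%) in QFM nuclei and 188 (2.58%) in EOM cells, and these were removed. Median mitochondrial shares of the kept barcodes were 0.459%, 0.190% and 11.9%. Each library was clustered by itself: counts were scaled to 10000 per barcode and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering at resolution 1 on 15 neighbours gave 25, 23 and 21 clusters. Clusters were named from 23 marker lists, by the mean z-score over clusters of the markers' log2 CPM (with 5 CPM added), and needed a score of 0.5 and 3 markers seen in at least 10% of barcodes. A cluster also stayed unnamed when its median depth was under 1/3 of the library's and none of its 10 leading genes was its own marker. This left 1 EOM nuclei cluster unnamed, with a median of 877 UMIs and 1.77% mitochondrial UMIs; its best-scoring list was type II myofibre. Myofibre clusters were split into type I-like, type II-like, junctional and mixed by a gap of 0.3 between the slow and fast scores. Junctional nuclei, 1.90% of EOM and 1.91% of QFM myonuclei, matched the neuromuscular markers in EOM and the myotendinous markers in QFM. They were therefore not compared as a subtype, but they stayed in the sums over all myonuclei. Mixed nuclei were 43.5% and 7.60%. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used, with seed 1.

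Counts were summed over each class and library and divided by their total to give CPM, and the log2 ratio of 2 sums was given with a conditional exact binomial interval. Sums have exact Poisson and shares Clopper-Pearson intervals, all at 95%. With 1 library per group there was no test and no p-value. A count of 0 was taken as 3 counts, and a fold given as at least some value is the ratio at that floor. Its 95% limit lies closer to no difference: for FAM240B in myonuclei the log2 ratio is 10.06 at the floor and 9.76 at the limit. A share of 0 was likewise taken at 3 nuclei, where the Clopper-Pearson limit for 0 of 10528 QFM nuclei is 0.0350%. The gene lists, class markers, comparisons and 27 alternative settings were fixed before the data were examined, while the 4 neural lists and the tests of the closing section were written after. In all, 19 gene lists were set and 18 had a measured member, the list of nuclear-retained RNA having none. A member was measured with at least 20 counts over both sums. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. In myonuclei the text names the 12 genes of largest and the 12 of smallest ratio with at least 50 CPM in the higher library, leaving out mitochondrially encoded and ribosomal protein genes. It also names every myosin heavy chain and up to 4 members of each list with at least 5 CPM. These rules chose 87 genes, a few of which are not named in the text. In other classes it names 5 genes each way with at least 100 CPM and a level above that in the same library's myofibres, and for cells against nuclei 5 each way with at least 50 CPM. Members named beyond these, such as EYA1 and HOXA10 in fibroblast-like nuclei, were chosen after their values were seen.

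Leading myosin chains were counted in nuclei with at least 3 myosin UMIs, and again after thinning each nucleus to 1000 UMIs. The level of free RNA was read from markers of 1 class in the nuclei of another. Counts for 16918 genes of the EOM against QFM comparison were simulated as Poisson draws, the counting error that the intervals assume. Spread between libraries was not simulated. In these counts 67, 67 and 66 genes were changed by 2, 4 and 8 times, raised or lowered in turn. They gave median folds of 2.00, 4.01 and 8.07 in the direction put in, with 97.0%, 100% and 93.9% of intervals holding the true value. Among 2000 unchanged genes 94.4% of intervals did so, 3.5% of 200 unchanged lists fell in the outer 5% of random lists, and a raised list of 33 genes reached percentile 100. Alternatives planned in advance, 27 in number, changed the barcode filter to every barcode, or to at least 500 genes, 1000 UMIs and a mitochondrial share of at most 5% in nuclei or 10% in cells. They also kept doublets, used resolutions 0.5 and 2, took all kept nuclei, thinned nuclei and asked for 5 myosin UMIs. Others scaled without the 50 most abundant genes or by the median ratio of genes with at least 50 counts, took list members from 1 count or each fibre subtype alone, scaled other classes without 200 myofibre genes and left mitochondrial and ribosomal genes out of cells against nuclei. A further 3 were chosen after seeing the data: leaving out myofibre clusters of which under 50% of nuclei stayed myofibre-like at resolution 2 (EOM cluster 8), leaving out myofibre clusters with a median mitochondrial share above 1%, and taking only myonuclei of at least 2000 UMIs.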

Results

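Single-nucleus and single-cell RNA profiles were collected from muscle of the cynomolgus macaque (Macaca fascicularis). Extraocular muscle (EOM) moves the eye, and the quadriceps femoris muscle (QFM) of the thigh served as the limb muscle. There were 3 libraries, 1 in each group: nuclei from EOM, nuclei from QFM and whole cells from EOM. The EOM nuclei library held 16491 barcodes and 61618999 UMIs (unique molecular identifiers, 1 per captured RNA molecule), the QFM nuclei library 12503 barcodes and 72590186 UMIs, and the EOM cell library 8979 barcodes and 12248405 UMIs. After filtering and removal of called doublets, 13970, 10528 and 7111 barcodes were kept, with medians of 2812, 4509.5 and 1142 UMIs. With 1 library per group no difference has a replicate check, so no test was made. All intervals are 95% intervals and cover counting error only.

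The first comparison asked which cell types made up the nuclei of each muscle. Myofibre-like nuclei, the nuclei of the contractile syncytium, made up 56.5% of EOM nuclei (Clopper-Pearson interval 55.7 to 57.3) and 70.5% of QFM nuclei (69.6 to 71.3). Nuclei like fibro-adipogenic progenitors or fibroblasts, the collagen-producing stromal cells, made up 16.6% (16.0 to 17.2) in EOM and 10.2% (9.64 to 10.8) in QFM. Endothelial-like nuclei were at 9.11% and 9.54%, satellite cell-like nuclei, the muscle stem cells, at 4.01% and 3.77%, and macrophage- or monocyte-like nuclei at 2.63% and 2.45%, with overlapping intervals in each of these 3 classes. Mural-like nuclei (pericytes or smooth muscle) were at 2.999% in EOM and 2.19% in QFM, T or NK cell-like nuclei at 0.966% and 0.408%, Schwann- or glial-like nuclei at 1.05% and 0.294%, and mast cell-like nuclei at 0.422% and 0.0950%. Tenocyte-like nuclei were at 0.236% in EOM, and 0 of 10528 QFM nuclei lay in a cluster of that name; taking 0 as 3 nuclei, this allows a share of up to 0.0285% in clusters so named. Perineurial-like nuclei (0.3799%) and adipocyte-like nuclei (0.180%) formed clusters in QFM, and 0 of 13970 EOM nuclei lay in clusters of these names, which allows up to 0.0215%. A further 767 EOM barcodes (5.49%) formed 1 unnamed cluster. The EOM myofibre-like share includes cluster 8, with 1884 nuclei and a median of 1473.5 UMIs, and was 49.7% without it. With called doublets kept, the EOM shares were 41.5% myofibre-like, 22.8% fibroblast-like and 15.6% endothelial-like; at clustering resolution 2 the endothelial-like share was 13.8%, the mural-like 4.76% and the macrophage-like 5.39%.

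**Figure D1:**
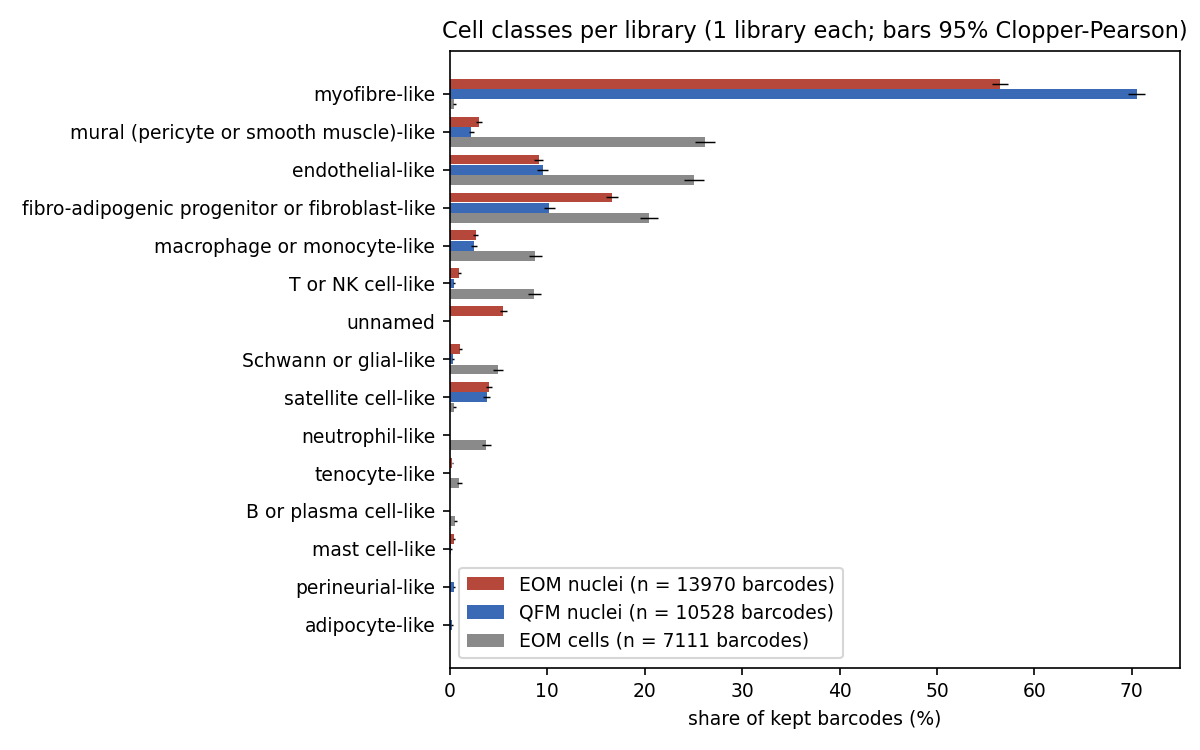
Horizontal bars give the share of kept barcodes (percent, x axis) in each cell class (y axis) for the 3 libraries, and whiskers are 95% Clopper-Pearson intervals of counting. Myofibre-like nuclei fill 56.5% of the EOM nuclei and 70.5% of the QFM nuclei but 0.464% of the EOM cells.

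The next comparison concerned the myosin heavy chains, the motor proteins that set the contraction speed of a fibre. MYH13, the extraocular myosin, held 48.8% of the UMIs of the 6 named chains in EOM myonuclei (interval 48.7 to 48.9) and 0.0797% in QFM. MYH15, an ancient slow-tonic type of chain, held 17.1% in EOM and 0.0111% in QFM. MYH7, the slow or beta-cardiac chain, held 25.2% (25.01 to 25.3) in QFM and 1.42% in EOM. The chain named MYH3, the embryonic chain, held 74.6% in QFM and 28.6% in EOM. MYH4 (a fast chain) was at 3.99% and 0.0560%, and MYH6 (the alpha-cardiac chain) at 0.116% and 0.130%. On the log2 scale EOM over QFM, MYH15 stood at 12.09 (11.62 to 12.62), MYH13 at 10.76 (10.58 to 10.95), MYH4 at 7.66 (7.45 to 7.88), MYH6 at 1.34 (1.17 to 1.51), MYH7 at -2.65 (-2.68 to -2.62) and MYH3 at 0.12 (0.11 to 0.13). The MYH3 direction was not stable: it was 3.42 (3.37 to 3.47) in type I-like nuclei, -0.14 in type II-like nuclei and -0.0900 with median ratio scaling. These genes are close copies of each other, and the genes MYH1, MYH2 and MYH8 have no name in the nuclei tables, so each count is uncertain and the shares run over the named chains only.

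Per nucleus, among myonuclei with at least 3 UMIs of these chains, MYH13 led in 59.4% of EOM nuclei (58.3 to 60.5), MYH15 in 19.9%, MYH3 in 13.7% and MYH7 in 2.32%. In QFM, MYH3 led in 60.7% and MYH7 in 39.2%. The unthinned MYH13 share cannot be told from background, since MYH13 led in 63.4% of endothelial-like EOM nuclei, which should lack it (median 2625 UMIs, against 3639 in myonuclei). When every nucleus was thinned to 1000 UMIs, which left out 821 shallower EOM and 47 shallower QFM myonuclei, MYH13 led in 55.0% of all thinned EOM myonuclei and in 28.05% of endothelial-like nuclei. MYH15 then led in 19.5% of the EOM myonuclei against 2.44% of the endothelial-like nuclei, and MYH3 in 14.9% against 7.24%. In thinned QFM myonuclei MYH3 led in 57.8% and MYH7 in 29.2%, against 4.36% and 0.406% of endothelial-like nuclei; unthinned, those endothelial-like shares were 15.6% and 4.48%, at a median of 3655.5 UMIs against 5114 in myonuclei. By level, MYH13 stood at 10276 CPM in EOM myonuclei and 1390 CPM in endothelial-like nuclei.

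**Figure D2:**
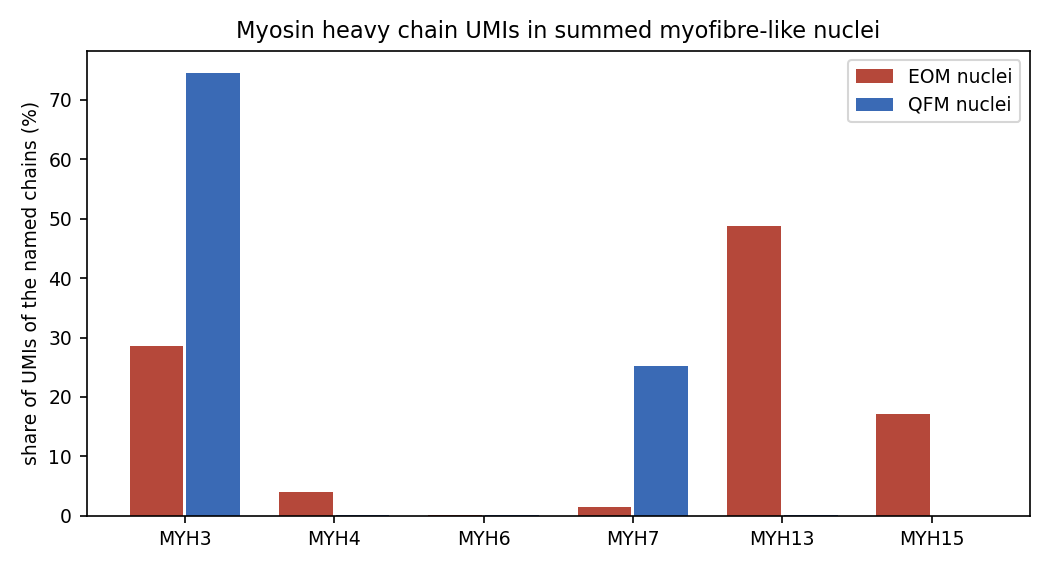
Bars give the share (percent, y axis) of each of the 6 named myosin heavy chains (x axis) among their summed UMIs in the myofibre-like nuclei of each muscle. MYH13 (48.8%), MYH3 (28.6%) and MYH15 (17.1%) hold the largest shares in EOM, and MYH3 (74.6%) and MYH7 (25.2%) in QFM.

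Across the whole transcriptome of the myonuclei, summed over 7892 EOM and 7420 QFM nuclei (35025749 and 42600905 UMIs), the genes highest in EOM relative to QFM included MYH15 and MYH13 beside genes of varied function. GRIA3, a subunit of AMPA-type glutamate receptors, stood at 798 CPM in EOM and 0.329 CPM in QFM, a log2 ratio of 11.25 (10.50 to 12.12). ROBO2, an axon guidance receptor, stood at 3338 and 3.47 CPM (log2 9.91), and LMX1A, a homeobox transcription factor, at 446 and 0.493 CPM (9.82). XKR4, also on the list of Schwann cell markers, was at 10.38, the secreted protein gene PI15 at 10.75 (9.20 to 13.02, with 3 QFM counts) and SLC35F4, a solute carrier family gene, at 8.60. HHLA2 had 2789 counts in EOM and 1 in QFM (interval 9.25 to 17.03). FAM240B and CPXCR1 had 0 QFM counts and were at least 1067-fold and at least 859.5-fold higher in EOM, taking 0 as 3 counts. The median of the 12573 genes compared lay 0.35 log2 units above 0 (0.27 with the most abundant genes trimmed, 0.14 with median ratio scaling), so lists are also given relative to it. Over all kept nuclei, where the counts of every class are pooled, GRIA3 was at 8.87, ROBO2 at 7.06 and LMX1A at 5.32. ROBO2 stood at 155 CPM in endothelial-like QFM nuclei, far above its level in QFM myonuclei, while GRIA3 and LMX1A were at 0.494 CPM there. The cause of the smaller ratios was not tested.

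The genes lowest in EOM relative to QFM included PFKFB1, an isoform of the enzyme that makes and breaks down a key activator of glycolysis, at 0.485 CPM in EOM and 720.2 CPM in QFM (log2 -10.54, interval -11.31 to -9.86). SLC36A2, an amino acid transporter, stood at -8.70, the transcription factor SIM1 at -8.34 and LGR5, a receptor of R-spondins, at -8.00. Sarcomere genes followed: MYOM2, a protein of the M-band, at -6.57 (-6.69 to -6.46), ANKRD2, a stretch-responsive titin-associated protein, at -6.51, the slow light chain MYL3 at -5.54 and the fast-fibre actinin ACTN3 at -5.32. The immediate-early gene FOS was at -5.59, BTG2, an antiproliferative gene, at -5.03, C1orf21 at -5.28 and the lysine methyltransferase SMYD2 at -4.75. Without cluster 8, SLC36A2 was at -9.35, BTG2 at -5.62 and SMYD2 at -5.47, and over all kept nuclei they were at -7.84, -3.96 and -3.36, with LGR5 at -6.95 and C1orf21 at -4.03. FOS was at -4.85 under the stricter barcode filter, and its EOM value rests on 39 counts.

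Contractile and developmental lists moved apart. Of 10 measured slow fibre sarcomere genes, 8 were at least 2-fold lower in EOM, 1 higher and 1 within 2-fold (median log2 -2.70, relative to all genes -3.04, below every one of 10000 random matched lists). The lower genes included MYL2 (-3.92), TNNC1 (-3.43) and ATP2A2 (-3.40), the slow calcium pump. Of 10 fast fibre sarcomere genes, 5 were lower, 2 higher and 3 within (median -0.97, relative -1.32, percentile 0.91): ACTN3 and the Z-disc gene MYOZ1 (-2.49) were lower, and MYH4 and the calcium buffer PVALB (5.35, interval 5.12 to 5.58) were higher. Developmental muscle isoforms were higher in 6 of 7 members, lower in 0 and within in 1 (median 3.03, relative 2.68, percentile 99.91), with TNNT2, the cardiac and embryonic troponin T, at 7.96, ACTC1, the cardiac actin, at 5.41, IGF2 at 3.03 and NCAM1 at 1.78. NCAM1 reached 2111 CPM in satellite cell-like EOM nuclei and 123 CPM in EOM myonuclei, so it is not clear of free satellite cell RNA. The myosin heavy chain list had 4 members higher, 1 lower and 1 within (median 4.50, relative 4.15, percentile 100). Without cluster 8 the developmental median and IGF2 were at 1.85, without mitochondria-rich clusters both were at 3.89, and over all kept nuclei the median was 1.37. Under the stricter filter ACTC1 was at 6.79. Type I-like nuclei were 13.5% of EOM and 36.4% of QFM myonuclei, and type II-like nuclei 41.1% and 54.1%. The type I-like nuclei were unlike in their myosins. In EOM, MYH15 (3920 CPM) stood above MYH7 (1766 CPM), while in QFM MYH7 was at 3944 CPM and MYH15 at 0.406 CPM. The EOM order held in cluster 14 (MYH15 5377 CPM, MYH7 1660 CPM) and not in cluster 21 (1228 and 1960 CPM). MYH15 was highest in mixed EOM cluster 4, at 9867 CPM. In type I-like nuclei alone the slow list stood at -1.58 (7 of 10 lower) and ATP2A2 at -3.46, and in type II-like nuclei at -0.0586 and 0.28. The fast list was at 0.93 in type I-like and -0.97 in type II-like nuclei, although 7 members of each list had defined those subtypes. In EOM, PVALB stood at 43.1 CPM in type I-like and 42.2 CPM in endothelial-like nuclei. The fast list's type I-like value is therefore not clear of free myofibre RNA.

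Genes of the neuromuscular junction were mostly higher in EOM, while calcium handling genes went both ways and most membrane excitability genes were within 2-fold in all myonuclei together. Among 14 measured neuromuscular junction genes, 10 were at least 2-fold higher, 1 lower and 3 within 2-fold (median 1.68, relative 1.34, percentile 99.97). COL25A1, a muscle collagen needed for motor innervation, was at 5.43 (5.30 to 5.56), the acetylcholine receptor subunits CHRNA1 at 3.02 and CHRND at 2.28, and the receptor kinase MUSK at 2.98. Membrane excitability genes had 4 of 12 members higher, 0 lower and 8 within (median 0.25, relative -0.09, percentile 71.4), the highest being the calcium-activated potassium channels KCNMA1 (5.39) and KCNN2 (4.17). Relative to all genes 3 members were higher and 3 lower, and in type I-like nuclei alone 4 of 12 were higher and 6 lower (median -0.66). Calcium handling genes had 4 of 18 higher, 7 lower and 7 within (median -0.50, relative -0.85, percentile 1.27), with the exchanger SLC8A1 at 3.53 and the kinase CAMK2A at -3.60. Of 6 myotendinous junction genes, 2 were higher, 1 lower and 3 within (median 0.51, relative 0.16, percentile 63.7). They ran from COL24A1 at 4.36 and NAV3 at 1.55 to ANKRD1, a stretch-responsive gene, at -3.81. ITGA7 was at 0.17 and turned to -0.0432 with median ratio scaling. All these sums include the junctional nuclei, which matched neuromuscular markers in EOM and myotendinous markers in QFM. Type I-like and type II-like nuclei leave out these and the mixed nuclei. There the myotendinous list stood at 3.83 and 1.66, and the neuromuscular list at 1.74 and 1.71. Dystrophin-glycoprotein complex genes had 1 of 14 higher, 2 lower and 11 within (median -0.36, relative -0.71, percentile 7.46), with SNTB1 at -2.91 and SGCE at 1.68. Without cluster 8, SLC8A1 was at 2.39, NAV3 at 0.41, SGCE at 1.02 and SNTB1 at -3.51, and over all kept nuclei SLC8A1 was at 1.03 and SNTB1 at -1.77. SLC8A1 reached 2356 CPM in macrophage-like EOM nuclei and 70.3 CPM in myonuclei. COL24A1 and CHRNA1 were higher in satellite cell-like EOM nuclei (2391 and 401 CPM) than in EOM myonuclei (67.1 and 31.5 CPM), so their myonuclear values are not clear of free satellite cell RNA, and CHRNA1 was at 1.39 over all kept nuclei.

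The measured energy metabolism genes were mostly lower or close. None of 12 measured glycolysis and glycogen genes was at least 2-fold higher in EOM, 6 were lower and 6 within (median -0.87, relative -1.21, percentile 0.36), with hexokinase HK2 at -3.19 (-3.41 to -2.98) and PGAM2 at -2.57. The list holds 22 genes, and the others had no symbol. GPI, ALDOA, TPI1, GAPDH, PGK1, ENO3, PKM and LDHA are among those, so the median does not cover these glycolytic enzymes. Of 14 fatty acid oxidation genes, 1 was higher, 4 lower and 9 within (median -0.64, relative -0.99, percentile 0.04), with lipoprotein lipase LPL at -2.86, the uncoupling protein UCP3 at -2.35, PDK4 at -1.92 and the carnitine transferase CPT1B at 1.10. Of 24 mitochondrial respiration and biogenesis genes, 3 were higher, 3 lower and 18 within (median -0.09, relative -0.44, percentile 27.1); the nuclear receptors ESRRG (3.35) and PPARA (1.80) were higher and the respiratory subunits COX6A2 (-1.38) and COX7A1 (-1.18) lower. Atrophy and growth control genes had 3 of 15 members higher, 3 lower and 9 within (median -0.11, relative -0.46, percentile 17.9), with the growth factor IGF1 at 3.45 (2.504 without cluster 8, 1.55 over all kept nuclei), MUSTN1 at -4.19, SMAD3 at -2.95 and the ubiquitin ligase TRIM63 at -2.10. IGF1 reached 1265 CPM in satellite cell-like and 1242 CPM in macrophage-like EOM nuclei, against 41.6 CPM in myonuclei, so its myonuclear value is not clear of free RNA of these classes. In type II-like nuclei the mitochondrial list stood at 0.63 and the fatty acid list at 0.20.

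Positional transcription factors separated the libraries. HOXC9, a gene of the posterior body axis, had 0 counts in EOM myonuclei and 774 in QFM and was at least 212-fold lower. Of 10 measured limb and trunk patterning genes, 7 were at least 2-fold lower in EOM, 5 of them with 0 EOM counts, and 3 were higher (median -4.28, relative -4.63, percentile 0), the 3 being PAX7 at 3.89, MEOX2 at 2.61 and TBX15 at 1.54. Of 13 cranial muscle patterning genes, 8 were higher, 1 lower and 4 within (median 1.87, relative 1.52, percentile 99.9), with ALX4 at 5.29, DACH1 at 4.72, PAX3 at 3.98 and EYA2 at 3.58. The limb list's median leans on the floor of 3 counts, and was -0.69 in nuclei thinned to 1000 UMIs and -0.93 with every member of at least 1 count. Without cluster 8, MEOX2 was at 1.40 and EYA2 at 2.67, and over all kept nuclei MEOX2 was at -0.0368, PAX7 at 1.39, DACH1 at 1.17 and the cranial list at 1.25. PAX7 reached 1422 CPM in satellite cell-like EOM nuclei (97.6 CPM in myonuclei) and DACH1 868 CPM in endothelial-like ones (339.8 CPM in myonuclei), so free RNA of these classes can add to both.

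Matrix genes, and 9 of 18 satellite cell genes, were higher in EOM myonuclei together with markers of other cell types. Of 24 extracellular matrix genes, 16 were at least 2-fold higher, 0 lower and 8 within (median 2.07, relative 1.72, percentile 100), with TNC at 4.63, elastin ELN at 4.40, COL5A1 at 3.98 and FBLN1 at 3.74. Of 18 satellite cell state genes, 9 were higher, 2 lower and 7 within (median 0.91, relative 0.56, percentile 88.2), with PAX3 and PAX7 highest, NOTCH1 at 2.95 and CHRDL2 at 1.92 (0.58 without cluster 8). The median marker of fibro-adipogenic progenitors lay at 8.83% of its own-class level in EOM myonuclei and at 1.06% in QFM myonuclei, that of satellite cells at 4.65% and 0.484%, and that of endothelial cells at 5.08% and 0.715%. Without cluster 8 the fibro-adipogenic markers lay at 4.73% and the matrix median was 1.03, COL5A1 was at 3.35, FBLN1 at 3.12 and NOTCH1 at 2.08. Over all kept nuclei the satellite list stood at -0.0762, TNC at 1.11 and the matrix median at 0.27. Dissociation and stress genes were lower in EOM in 6 of 9 members, higher in 1 and within in 2 (median -1.90, relative -2.25, percentile 0), with JUN at -4.22 (-4.38 to -4.06), the nuclear receptor NR4A1 at -3.46 and ZFP36, which speeds mRNA decay, at -2.02.

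**Figure D3:**
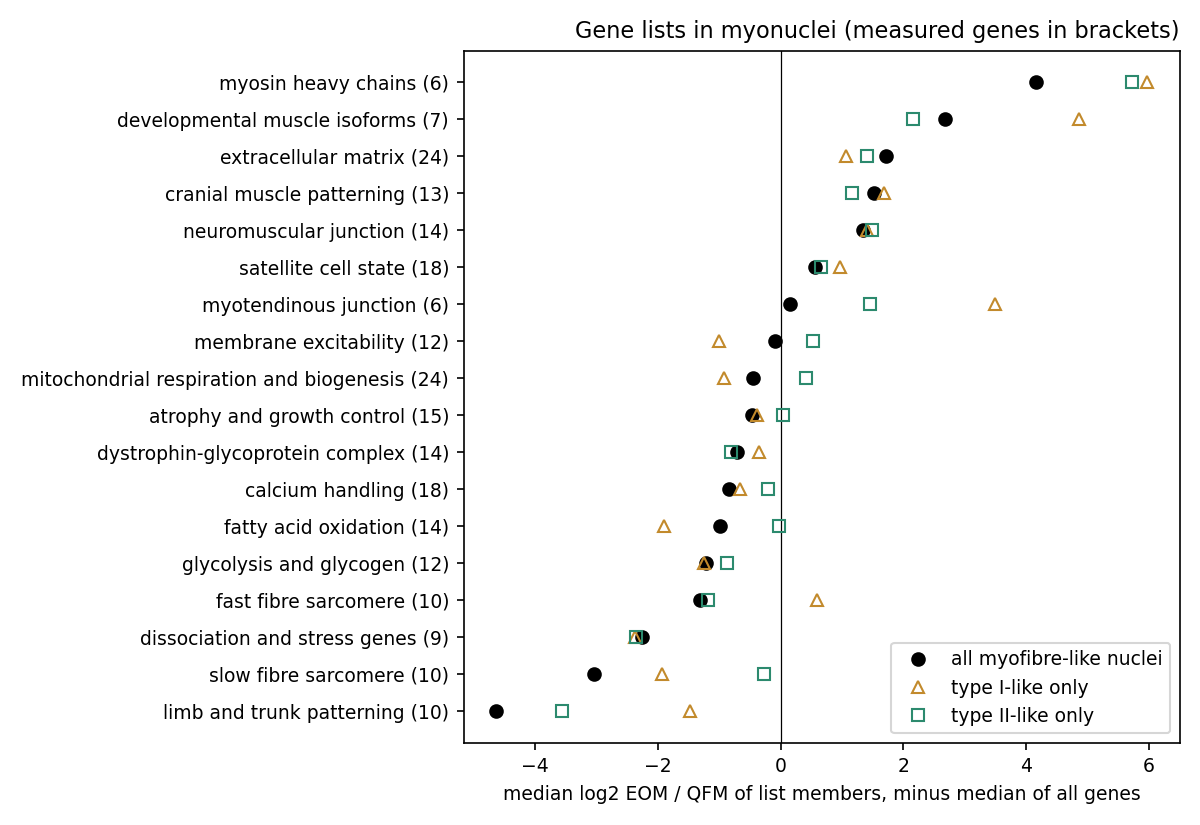
Points give the median log2 ratio, EOM over QFM, of each gene list after subtraction of the median of all genes (x axis), with the list and its number of measured genes on the y axis; circles are all myofibre-like nuclei, triangles type I-like and squares type II-like nuclei. The myosin heavy chain list lies at 4.15 and the limb and trunk list at -4.63, and the fast fibre list lies at 0.59 in type I-like and -1.19 in type II-like nuclei.

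The other classes with at least 100 nuclei in both muscles were compared in the same way, leaving out genes no higher there than in the same library's myofibres. Endothelial-like nuclei came from clusters 0, 1 and 24 in EOM and from 0, 9, 11 and 14 in QFM, the last led by lymphatic genes. In them the glucose transporter SLC2A1 was higher in EOM at log2 7.47 (6.34 to 8.92), the Wnt transcription factor LEF1 at 5.89, the lipid flippase ATP10A at 5.48 and the amino acid transporter SLC7A5 at 5.27. The thiamine transporter SLC19A3 had 405 counts in EOM and 1 in QFM (interval 6.34 to 14.14). The fatty acid binding protein FABP4 was lower at -4.29 (-4.70 to -3.92), as were RELN at -4.10, CDKN1C at -3.31, MGP at -2.73 and the basement membrane collagen COL4A1 at -2.59. RELN is on the lymphatic marker list, which scored best in QFM cluster 14 and in none of these EOM clusters. Its value can therefore reflect which clusters were pooled. With doublets kept, SLC2A1 was at 6.67, SLC7A5 at 3.78 and RELN at -3.23. Of 22 matrix genes, 6 were at least 2-fold higher and 3 lower in EOM (median 0.49).

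In nuclei like fibro-adipogenic progenitors (clusters 2, 3 and 18 in EOM, 12 and 16 in QFM), the serotonin receptor HTR2C was higher in EOM at 8.28 (6.92 to 10.16), the ephrin receptor EPHA7 at 7.40 (5.85 to 9.69, with 3 QFM counts), the peptidase TRHDE at 6.93, THSD4 at 6.82 and NECAB1 at 6.60. PRG4, the lubricating proteoglycan lubricin, was lower at -8.00 (-9.63 to -6.77), and so were CCBE1 at -5.46, the matrix protein ASPN at -5.00, RERG at -4.94 and CCN3 at -4.85; CCBE1 was at -4.77 with doublets kept. Of 24 matrix genes here 10 were lower in EOM and 0 higher (median -0.79), COL1A1 being at -2.47. Positional genes differed in these stromal nuclei too: 9 of 12 cranial patterning genes exceeded 2 times the level that free myofibre RNA would give. Of these, 6 were higher in EOM and 1 lower, with EYA2 at 6.24 and EYA1 at 5.03. Of 7 such limb and trunk genes, 0 were higher and 6 lower; HOXC9 had 0 counts in EOM and 199 in QFM, and HOXA10 had 0 and 88.

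In mural-like nuclei (clusters 15 and 16 in EOM, 10 in QFM), SGCZ, a sarcoglycan, stood at 7.56 (6.01 to 9.84, with 3 QFM counts), the glutamate receptor GRM7 at 6.75, EYA2 at 5.14, ADGRB3 at 5.07 and MEI4 at 5.07 (3 QFM counts). Lower were FABP4 at -5.62, NR4A1 at -4.25, S100A4 at -3.92 and JUN at -3.79. ADGRB3 reached 469.6 CPM in the unnamed EOM cluster, above its 293 CPM in mural-like nuclei, and was at 3.36 with doublets kept, as FABP4 was at -4.83. In macrophage- or monocyte-like nuclei (clusters 11 and 22 in EOM, 15 in QFM), S100A8, a calcium-binding protein of myeloid cells, had 0 counts in EOM and 1170 in QFM, at least 334-fold lower in EOM. S100A4 (-5.92), S100A10 (-4.67), TPPP3 (-4.48) and the peroxidase GPX1 (-4.34) were lower too. S100A8 was among the leading genes of QFM cluster 15, which held 6 macrophage markers and 1 neutrophil marker. It was also a leading gene of the neutrophil-like cluster of EOM cells. A difference in the mix of myeloid cells and one in expression cannot be told apart here. GRIA4 was at 5.58, with 159 CPM in the unnamed cluster, DENND2A at 3.70, PTPRT at 3.43, GPC5 at 3.36 and NAV3 at 3.01. With doublets kept, GPC5 was at 2.18, TPPP3 at -3.17 and GPX1 at -3.75. In satellite cell-like nuclei (cluster 12 in EOM, 13 in QFM), CYTIP was at 6.77 and the collagens COL6A6 and COL24A1 were at 5.74 and 4.93 (4.61 to 5.26). CDH20 had 0 QFM counts and was at least 67.4-fold higher in EOM, and the cold-sensing channel TRPM8 had 137 counts in EOM and 1 in QFM (4.59 to 12.41). Lower in EOM were S100A4 (-4.68), CDKN1C (-3.86), MUSTN1 (-3.45), ALDH3A1 (-3.36) and the myogenic factor MYF5 (-3.30). CYTIP was at 7.48 with doublets kept.

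The lists in these remaining classes moved less alike. Matrix genes had a median of -0.82 in mural-like nuclei (4 of 21 higher, 10 lower), 0.65 in macrophage-like nuclei (5 of 15 higher, 2 lower) and 0.02 in satellite cell-like nuclei (5 of 20 higher, 2 lower). The satellite cell state list lay at -0.16 in satellite cell-like nuclei (2 of 14 higher, 4 lower), 0.08 in endothelial-like, -0.64 in fibroblast-like, -0.29 in macrophage-like and 0.23 in mural-like nuclei. Free myofibre RNA put the median myofibre marker at 12.4% of its myofibre level in endothelial-like EOM nuclei and 26.3% in mural-like ones, against 6.76% and 15.1% in QFM. Above 2 times that level, 4 cranial genes in endothelial-like nuclei included 1 higher and 2 lower, 4 in mural-like nuclei 3 higher and 1 lower, 12 in satellite cell-like nuclei 6 higher and 3 lower, and 1 in macrophage-like nuclei none either way. For limb and trunk genes, 4 such genes in endothelial-like nuclei had 0 higher and 3 lower, 3 in mural-like nuclei 1 and 1, 2 in satellite cell-like nuclei 0 and 1, and 0 remained in macrophage-like nuclei. Stress genes were lower in each of the 5 classes, with medians of -1.21 in endothelial-like (0 of 7 higher, 4 lower), -1.90 in fibroblast-like (0 and 9 of 9) and -1.01 in macrophage-like (0 and 4 of 7). They were -1.97 in mural-like (0 and 6 of 7) and -1.90 in satellite cell-like nuclei (0 and 6 of 6).

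The last comparison set whole cells against nuclei of EOM, with genes and lists compared over the sum of each whole library and not within classes. The cell library held few myofibre-like barcodes, 0.464% (0.320 to 0.651). It held mural-like (26.2%), T or NK cell-like (8.63%), Schwann- or glial-like (4.91%), neutrophil-like (3.74%), tenocyte-like (0.956%), B or plasma cell-like (0.534%) and satellite cell-like cells (0.450%). Endothelial, fibroblast and macrophage clusters were not matched as classes between the preparations. Endothelial clusters 10, 8, 17 and 15 held 10.4%, 7.76%, 4.85% and 2.05%, fibroblast clusters 1, 16 and 2 held 15.8%, 4.46% and 0.127%, and macrophage clusters 0, 12 and 11 held 3.11%, 3.07% and 2.55%. By their leading genes the names of clusters 10, 2 and 12 are doubtful, since those 10 genes held 0 markers of the named class and 1 of another (perineurial, satellite cell and lacrimal gland). The doubt is not equal. Their scores were 1.79, 0.57 and 1.24, and 15, 13 and 8 markers of the named class were seen in at least 10% of barcodes. The mural-like share was 12.2% with doublets kept, and under the stricter filter the myofibre-like share was 1.43% and the T or NK cell-like share 2.52%. Dissociation and stress genes were higher in cells: all 10 measured members were at least 2-fold higher (median log2 cells over nuclei 7.74, against -0.45 for all genes), and the chemokine CXCL8 stood at 12.47 (11.24 to 14.09) and S100A8 at 12.28. ATP6V0C, a proton pump subunit, was at 12.85 with 3 counts in nuclei, NDUFA11, a subunit of respiratory complex I, had 0 counts in nuclei and was at least 4569.7-fold higher in cells, and NGRN, of mitochondrial ribosome assembly, had 2024 counts in cells and 2 in nuclei (10.69 to 15.59). Lower in cells were MYH13 at -10.54 (-11.00 to -10.11), XKR4 with 1 count in cells and 53921 in nuclei, and REV3L, a DNA polymerase subunit, with 0 counts in cells and at least 2899-fold lower. BEST3 had 2 counts in cells and 48454 in nuclei, and CALR3, with 3 counts in cells, was at -10.07 (-12.35 to -8.53).

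By list, cells were higher in matrix genes (15 of 25 at least 2-fold higher, 4 lower, median 1.72) and in limb and trunk genes (4 of 7 higher, 2 lower, median 3.05). Muscle lists were lower in cells: myosin heavy chains (5 of 5 lower, median -8.19), membrane excitability (11 of 12 lower, 1 higher, -4.42), fast sarcomere (9 of 10 lower, 0 higher, -4.66) and neuromuscular junction (12 of 14 lower, 1 higher, -3.94). The same held for developmental isoforms (5 of 6 lower, 1 higher, -3.49), calcium handling (13 of 18 lower, 1 higher, -3.01), cranial patterning (10 of 13 lower, 3 higher, -2.96), glycolysis (10 of 11 lower, 0 higher, -2.70) and the dystrophin complex (9 of 14 lower, 2 higher, -2.55). Smaller medians belonged to atrophy and growth control (-2.02, 11 of 15 lower, 2 higher), myotendinous junction (-1.97, 5 of 6 lower, 0 higher) and mitochondrial genes (-1.89, 15 of 22 lower, 5 higher). The least were satellite cell state (-1.20, 10 of 18 lower, 6 higher), slow sarcomere (-0.88, 4 of 9 lower, 2 higher) and fatty acid oxidation (-0.30, 5 of 14 lower, 3 higher; 0.03 without mitochondrially encoded and ribosomal protein genes). These ratios compare whole libraries, so the class mix enters every gene and list value. Myofibre-like barcodes were 0.464% of cells and 56.5% of nuclei, mural-like 26.2% and 2.999%, and neutrophil-like 3.74% and 0%. The preparations also differ in gene models as well as in compartment, since the cell table names its genes from another annotation. A value of a single gene here can therefore reflect its model.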

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

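Every test weighed in this part was chosen after the pattern had been seen.

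In 4 gene lists the myonuclear difference between the muscles pointed one way in type I-like and the other way in type II-like nuclei, relative to all genes; these opposite directions were not tested, since each muscle has 1 library. The fast fibre sarcomere list stood at 0.59 in type I-like and -1.19 in type II-like nuclei, and 7 of its members had defined those subtypes. In EOM, PVALB stood at 43.1 CPM in type I-like and 42.2 CPM in endothelial-like nuclei, and MYH4 at 172 and 110 CPM. The median myofibre marker lay at 12.4% of its myofibre level in endothelial-like EOM nuclei and at 6.76% in QFM. The list's type I-like value is therefore not clear of free RNA of fast fibres, though other members were not set against that level. The mitochondrial respiration and biogenesis list stood at -0.92 and 0.41. The membrane excitability list stood at -1.002 and 0.52, and the atrophy and growth control list at -0.39 and 0.0392. Separately, 767 barcodes of the EOM nuclei formed the unnamed cluster, which entered no class.

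The gene named MYH3, the embryonic myosin, was abundant in QFM myonuclei, at 5535 CPM. An embryonic programme is argued against, since the other 6 named developmental genes had a median of 1.03 CPM in QFM type II-like nuclei, where MYH3 stood at 9701 CPM. MYH3 was 38.5 times as high in type II-like as in type I-like QFM nuclei. This is consistent with reads of other fast chains, such as the neighbours MYH1 and MYH2 that carry no name in these tables, being counted under MYH3, but the ratio had been seen before the test was set and the idea remains a hypothesis. A true use of MYH3 by fast fibres stays open.

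The unnamed EOM cluster carried neuronal transcripts, with SNAP25 at 855 CPM and SYT1 at 568 CPM. Of 10 named pan-neuronal genes (median 193 CPM, 2 of them at 5 CPM or more in QFM myonuclei), SNAP25 and CELF4 were left out of the tests as leading genes of the cluster, though others had also been seen. Free RNA spread over the whole library is argued against by the median ratio of 41.9 between this cluster and endothelial-like nuclei for the 8 remaining genes, and motor neurons by a median of 0 CPM for 6 motor neuron markers (1 also on a fixed list), against 141 CPM for 4 central neurotransmitter genes such as GAD1 (352 CPM) and GAD2 (201 CPM), of which 1 reached 5 CPM in QFM myonuclei. The 8 genes had a median of 146 CPM, above the level set for nuclei or RNA of central neurons in the suspension or library. That level cannot tell central from other neurons, since pan-neuronal genes are shared by neurons of every kind. The cluster had also been noticed for such genes, so no conclusion is drawn from this test. The 7 markers of central glia had a median of 0 CPM (1 of them at 5 CPM or more in QFM myonuclei). Myofibre RNA was also high, with MYH13 at 6063 CPM, and no source within the muscle other than motor neurons was tested.

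Stress and immediate-early genes were lower in EOM than in QFM nuclei. A response of myofibres alone is argued against, as all 5 other classes also had list medians more than 1 log2 unit under that of all genes. Spill of QFM myofibre RNA into the other QFM classes is argued against too: in 5 of 5 classes the lower quartile of the stress genes, as a percent of their myofibre level, lay above the upper quartile of the myofibre markers (medians 82.5% to 172%, and 6.70% to 15.1%). An earlier form of this test, set before its value was seen, asked for medians above the myofibre level and gave 3 of 5 classes, within the spread of the genes, and FOS alone stood at 6.46% in endothelial-like nuclei, no higher than the markers. A difference in handling between the libraries and a difference between the muscles cannot be told apart, because each muscle is 1 library and both would give the median of -1.91 seen over the 6 classes.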

How the results depend on the processing

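The 3 alternatives that leave out scattering or mitochondria-rich myofibre clusters or shallow myonuclei were chosen after seeing the data. Of 1218 alternative values for 87 named genes in myonuclei, 8 reversed, in 5 genes. In other classes 0 of 100 did, and 6 of 18 lists reversed at least once, counting only those whose counting interval leaves out 0. Atrophy and growth control, whose interval includes 0, was at -0.11 and was 0.25 in type II-like nuclei. The cause was not tested for any value below. No paired analysis was possible because each group holds 1 library. Ratios of genes at 0 counts are taken at the floor of 3 counts, and those of genes near 0 counts have wide intervals.

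The EOM myofibre-like share was 57.7% over every deposited barcode, 59.5% under the stricter filter, 41.5% with doublets kept, 47.9% at resolution 2 and 49.7% without the scattering cluster; the fibroblast-like share was 15.8%, 22.8%, 15.5% and 19.2% under the same settings apart from the stricter filter. In QFM with doublets kept these were 65.6% and 11.6%. The myofibre-like share of EOM cells was 1.43% under the stricter filter. Myonuclei led by MYH13 in EOM were 55.6% when thinned, 60.9% under the stricter filter, 57.8% with doublets kept, 58.1% at resolution 2, 55.6% without the scattering cluster and 62.8% over all kept nuclei. Myonuclei led by MYH7 in QFM were 33.4% when thinned, 37.2% with doublets kept and 37.7% over all kept nuclei.

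Median log2 of fast fibre sarcomere was -0.89 under the stricter filter, -0.86 with doublets kept, -0.94 at resolution 2, -1.02 over all kept nuclei, -1.03 thinned, -0.94 from 2000 UMIs, -0.82 without the scattering cluster, -0.64 without mitochondria-rich clusters, -1.04 trimmed, -1.18 with median ratio scaling, and 0.93, a reversal, in type I-like nuclei. Median log2 of slow fibre sarcomere was -2.59 with doublets kept, -2.36 thinned, -1.58 and -0.0586 in type I-like and type II-like nuclei, -2.59 without the scattering cluster, -2.77 trimmed and -2.91 with median ratio scaling. Median log2 of glycolysis and glycogen was -0.83 under the stricter filter, -0.79 with doublets kept, -0.94 over all kept nuclei and -0.96 thinned. It was -0.77 without the scattering cluster, -0.74 without mitochondria-rich clusters, -0.94 trimmed, -1.08 with median ratio scaling, and -0.91 and -0.66 in type I-like and type II-like nuclei. Median log2 of mitochondrial respiration and biogenesis was -0.58 in type I-like and, reversed, 0.63 in type II-like nuclei, -0.0601 without the scattering cluster, -0.0488 without mitochondria-rich clusters, -0.17 trimmed and -0.30 with median ratio scaling. Other reversals were median log2 of calcium handling (0.00293) and of fatty acid oxidation (0.20) in type II-like nuclei, of membrane excitability (-0.66) in type I-like nuclei and of satellite cell state (-0.0762) over all kept nuclei.

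Among genes, MYH13 was at 10.35 over all kept nuclei, 11.04 in type II-like nuclei and 10.55 with median ratio scaling. MYH3 reversed to -0.00296, -0.14 and -0.0900 under the same settings, ATP2A2 to 0.28 in type II-like nuclei, ITGA7 to -0.0724 in type I-like nuclei and -0.0432 with median ratio scaling, and MEOX2 to -0.0368 and CHRDL2 to -0.11 over all kept nuclei.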

Other observations

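The observations below were chosen after their values were seen, and none was tested.

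Within type I-like nuclei (1064 in EOM, 2700 in QFM), several junctional and developmental genes stood far apart between the muscles. These nuclei were unlike in their myosins. In EOM, MYH15 (3920 CPM), MYH3 (2690 CPM) and MYH13 (2014 CPM) stood above MYH7 (1766 CPM). For MYH15 this order held in cluster 14 (5377 against 1660 CPM) and not in cluster 21 (1228 against 1960 CPM). MYH15 was highest in mixed EOM cluster 4, at 9867 CPM. In QFM, MYH7 stood at 3944 CPM and MYH15 at 0.406 CPM. Mixed nuclei, 43.5% of EOM and 7.60% of QFM myonuclei, were in neither subtype. COL25A1, a muscle collagen needed for motor innervation, was at 3394 CPM in EOM and 4.35 CPM in QFM (log2 9.61, interval 9.28 to 9.95), and the cardiac and embryonic troponin TNNT2 at 1449.8 and 0.232 CPM (12.61, 11.25 to 14.48, with 4 QFM counts). The acetylcholine receptor subunits CHRNA1 (5.69) and CHRND (3.71), the fetal subunit CHRNG (2.55), the receptor kinase MUSK (5.51) and the adhesion molecule NCAM1 (5.203) were also higher in EOM, as was the potassium channel KCNN2 (7.15). In type II-like nuclei the ratios were 8.94 for TNNT2, 5.60 for COL25A1, 3.08 for CHRNA1, 1.71 for CHRND, 1.52 for CHRNG, 3.93 for MUSK, 2.05 for NCAM1 and 2.87 for KCNN2. In type II-like EOM nuclei TNNT2, COL25A1, CHRNA1 and CHRND stood at 96.2, 54.7, 6.20 and 4.96 CPM. In endothelial-like EOM nuclei they stood at 63.9, 40.3, 6.11 and 3.34 CPM, so these type II-like values are not clear of free RNA. NCAM1 was at 68.4 against 46.1 CPM. MUSK (102 against 22.8 CPM) and KCNN2 (251 against 38.1 CPM) stood further above that level. Satellite cell markers lay at 4.53% of their own-class level in type II-like EOM nuclei and 0.608% in QFM, and at 4.14% and 0.273% in type I-like nuclei. NCAM1 and CHRNA1 stood at 2111 and 401 CPM in satellite cell-like EOM nuclei and at 68.4 and 6.20 CPM in type II-like ones, so their type II-like ratios are not above what free satellite cell RNA would give. As lists in type I-like nuclei, neuromuscular junction genes had 9 of 13 members at least 2-fold higher in EOM and 0 lower (median 1.74), and developmental isoforms 7 of 7 (median 5.203). In type II-like nuclei the junction list had 9 of 13 higher and 0 lower (median 1.71), and developmental isoforms had 5 of 6 higher (median 2.36). Whether the subtypes differ was not tested.

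Fatty acid oxidation genes, which burn lipid in the mitochondria, were mostly lower in type I-like EOM nuclei, whose myosins differed from those of type I-like QFM nuclei as given above. Of 14 fatty acid oxidation genes there, 10 were at least 2-fold lower in EOM and 0 higher (median -1.56), among them LPL at -4.10 (-4.39 to -3.83). Of 24 mitochondrial respiration and biogenesis genes in the same nuclei, 7 were lower, 1 higher and 16 within 2-fold (median -0.58). In type II-like nuclei 7 of 24 mitochondrial respiration and biogenesis genes were at least 2-fold higher in EOM and 0 lower, with a median of 0.63.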
